A study of Rattus norvegicus with 61 samples.

How the data were processed

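The values analysed were the deposited whole-number read counts per gene, 1 table per brain region, for 30 striatal and 31 cerebellar libraries. Per the submitters' processing notes, FastQC, HISAT2 and the rn6 build were used, with no versions given. The counting tool, the strand setting, the treatment of reads with several positions and the gene annotation are not given in the sources used here. Per the labels' protocols, tissue punches were lysed in TRIzol, RNA was cleaned on RNeasy columns, and messenger RNA was enriched by poly(A) capture or removal of ribosomal RNA, without saying which library had which. The tables held 14231 genes (striatum) and 14129 genes (cerebellum), of which 14163 and 14063 had a symbol for their NCBI Gene ID. The lowest total of a gene over the libraries of a region was 10 reads in each table, so genes with fewer reads are not analysed here. No genome of the rn6 build was at hand, and no coordinates were used.

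Counts were scaled by trimmed mean of M values (TMM), and genes with low counts were removed with filterByExpr, which left 12267 genes in the striatum, 11946 in the cerebellum and 12616 in the fit of both regions. Each region had its own quasi-likelihood fit in edgeR with robust dispersions and 4 exposure groups. Each loading was tested against sham, together with a test of any difference among the groups and a linear trend with percent loading. The difference between regions in the high versus sham change was an interaction term in a fit of all 61 libraries. All p values were two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM (counts scaled to a common library total) with TMM factors, given as mean ± SD over libraries. Library means over gene lists are log2 CPM with a prior count of 2. Fold changes are log2 with their standard error.

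The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. In each loading versus sham comparison the rule named up to 10 genes per direction past the threshold, filled to 5 per direction by smallest p, together with region markers and genes of the exposure's possible targets. It also named up to 4 members of each list past its test, 5 genes per direction for the trend and the interaction, and 10 for any exposure. The 43 fixed lists held cell type markers, tissues next to the punches, signalling systems, stress and hormone responses, and housekeeping complexes. Lists with fewer than 3 tested members were left out, so that 41 lists were tested in the striatum and 42 in the cerebellum. Lists were tested against all other genes with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were tested again with the correlation estimated from the data, with fry, and by exact permutation of library means over every split of the libraries compared. No camera call in any comparison held with the estimated correlation, and fry called no list.

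The alternatives fixed in advance were size factors of the relative log expression type (RLE) in edgeR, DESeq2, limma-voom with sample quality weights, no filter, and a filter at a mean CPM of 1. They also included a block for the run of 15 animal numbers, a fit of the compared groups alone, leaving out each library in turn, and, for the interaction, a block for the animal. The labels name 4 cohorts of rats 3 weeks apart but give no cohort per rat, so the runs stand in for cohorts and that a run is a cohort is inferred. Alternatives added after seeing the data left out libraries standing apart, the libraries of animal 17 or, for the lists, each library in turn. Others added the library means of ribosomal protein and region neuron genes as covariates, or 2 surrogate variables. The exact permutation of list means was also added after seeing the data. A library stood apart when its mean over the ribosomal protein list, or over the list of its region's own neurons, differed by more than 1 log2 unit from the median of its region. Results for these lists, and for transcripts that vary with them, therefore follow in part from the choice in that alternative and with the covariates. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

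The procedure was tested on simulated data, drawn from negative binomial counts with the group sizes, depths and dispersions of each region and 67, 67 and 66 genes changed by 1.5, 2 and 4-fold. In the striatum edgeR recovered 32.8, 76.1 and 89.4% of them for the low loading, 40.3, 82.1 and 97.0% for the medium loading and 23.9, 68.7 and 92.4% for the high loading. In the cerebellum it recovered 2.99, 32.8 and 75.8%, 5.97, 29.9 and 71.2%, and 10.4, 29.9 and 81.8%. Recovery for any exposure was 37.3, 74.6 and 97.0% (striatum) and 19.4, 32.8 and 86.4% (cerebellum). For the trend it was 41.8, 67.2 and 93.9% and 17.9, 32.8 and 84.8%, with the fold taken at the high loading, and for the interaction 4.48, 20.9 and 68.2%. Unchanged genes called numbered 2 to 7 with edgeR, 20 and 21 with DESeq2 and 3 and 8 with limma-voom, and camera recovered a list of astrocyte genes raised 1.5-fold in each region. Genes were drawn independently, without the tissue and RNA differences that many genes share in the real libraries. The simulation therefore cannot show how often genes or lists are called wrongly in the real data. Random splits of the real libraries into groups of the same sizes called a median of 8 to 14 lists.

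Columns were matched to samples by name, with 0 left unmatched. Animal numbers in the titles placed striatum and cerebellum of the same number together for 29 rats. Residual profiles of those pairs, after removing region and exposure means, had a median correlation across genes of 0.345 (range -0.240 to 0.818), against 0.0506 for different animals, and 21 of the 29 were above 0.1. The best match was the library of the same number for 5 rats. Genes are not independent replicates in these correlations. No pair of libraries was a copy of another: the closest pairs had a chi-square per degree of freedom of 3.26 (striatum low 53 and medium 54) and 2.61 (cerebellum medium 57 and high 58).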

Results

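The libraries came from male adolescent rats that carried a subcutaneous polymer implant for 28 days from postnatal day 28. The implant was loaded with 0% (sham), 1% (low), 5% (medium) or 10% (high) 4-OH-PCB52, a hydroxylated metabolite of a polychlorinated biphenyl. The series asks which genes differ in the striatum and the cerebellum after this exposure. Striatal libraries numbered 8 for sham, 6 for low, 8 for medium and 8 for high, and cerebellar libraries 7, 8, 8 and 8. Totals ran from 5850199 to 10944066 reads in the striatum (median 7139973) and from 5420458 to 10994625 in the cerebellum (median 7223058). Libraries are named by group and animal number, and the 3 comparisons of a region share its sham libraries, so they are not independent.

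Transcripts of each region's main neurons separated the tissues. In sham striatum, Ppp1r1b (NCBI Gene ID 360616), which encodes the dopamine-regulated phosphatase inhibitor of projection neurons, stood at 3043 ± 1208 CPM (n = 8), against 272 CPM in sham cerebellum (n = 7). The dopamine receptors Drd1 (24316) and Drd2 (24318) stood at 311 and 277 CPM in sham striatum, with Adora2a (25369), an adenosine receptor of the indirect pathway, at 537 CPM and the opioid precursor Penk (29237) at 1328 CPM. In sham cerebellum, Gabra6 (29708), a GABA receptor subunit of granule cells, stood at 787 ± 138 CPM (n = 7), against 1.06 CPM in sham striatum. Cbln1 (498922) and Cbln3 (501998), secreted synapse organisers of granule cells, stood at 1345 and 428 CPM there. Pcp2 (304195) and Car8 (297814), transcripts of Purkinje cells, had a median of 397 CPM and a mean of 1151 CPM.

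Within a region, libraries of the same exposure varied widely in their main neurons and in ribosomal protein transcripts. The mean over the list of striatal projection neurons was 4.54 in sham 17, 5.04 in low 20 and 5.23 in high 13, against group means of 7.84 (sham), 7.73 (low), 8.48 (medium) and 7.86 (high) log2 CPM. The mean over the list of cerebellar granule cells was 4.30 in low 22, 6.68 in medium 40 and 7.49 in sham 48, against group means of 8.44, 8.01, 8.17 and 8.19. Ribosomal protein transcripts in the cerebellum averaged 11.9 in high 43, 10.9 in high 28, 10.5 in high 59, 9.93 in sham 48 and 9.74 in medium 24, against a sham mean of 7.80 and a high mean of 8.64 log2 CPM. In all, 8 of 30 striatal libraries (2 sham, 1 low, 2 medium, 3 high) and 10 of 31 cerebellar libraries (1, 2, 4 and 3) stood apart by more than 1 log2 unit on either list. The leading principal component held 35.9% of the variance in the striatum and 71.2% in the cerebellum.

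**Figure D1:**
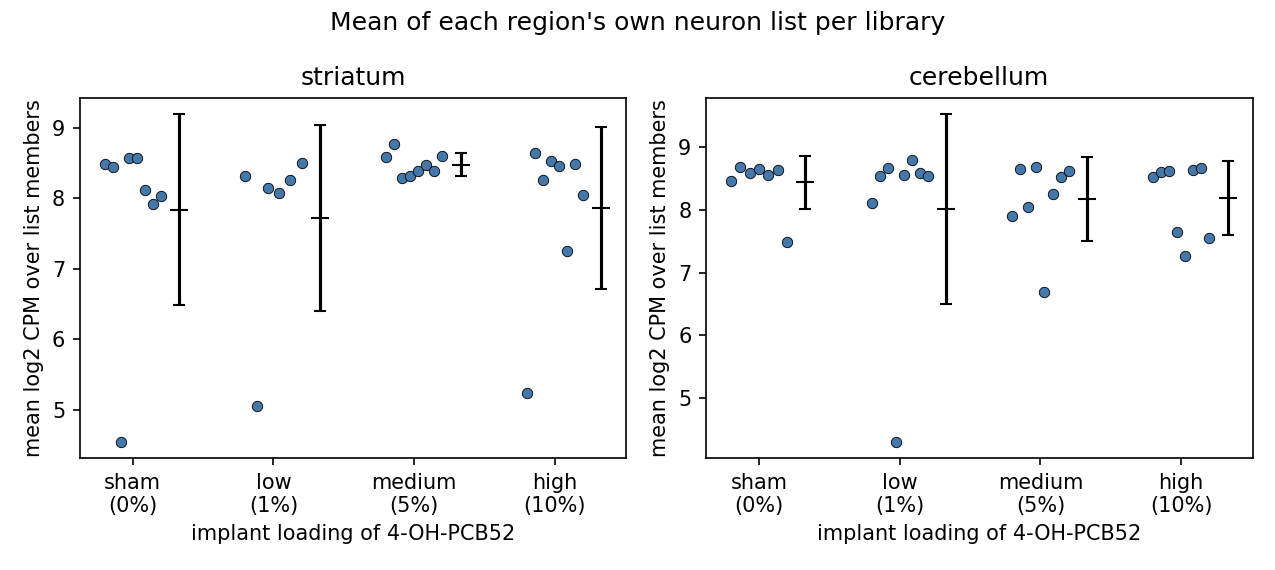
Mean log2 CPM per library over the list of striatal projection neurons (striatal libraries) and over the list of cerebellar granule cells (cerebellar libraries), by exposure group. Each point is a library and bars are mean ± SD.

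In the striatum at the low loading, transcripts of glia and vessels stood above sham and, with sham 17 included, those of the choroid plexus, the epithelium that makes cerebrospinal fluid, stood below, while no single gene passed the test. All 19 astrocyte transcripts were higher, with a median log2 fold change of 0.36, among them Aldh1l1, a folate enzyme (0.45 ± 0.15), and Fgfr3, a growth factor receptor (0.46 ± 0.16, n = 6 low and 8 sham). All 18 endothelial transcripts (median 0.32; the receptor Tie1 0.48 ± 0.17, the glucose transporter Slc2a1 0.28 ± 0.12) and 13 of 14 mural cell transcripts (median 0.53; Rgs5 0.63 ± 0.25, Pdgfrb 0.56 ± 0.23) were higher. All 71 nuclear-encoded respiratory chain transcripts were lower (median -0.24; Atp5f1a -0.23 ± 0.13), as were 77 of 79 ribosomal protein transcripts (median -0.21). The difference of respiratory chain library means went from -0.18 to -0.09 without sham 49 and to -0.11 without sham 48. The choroid plexus list had a median of -2.65, with Ttr (24856), the thyroid hormone carrier of cerebrospinal fluid, at -5.46, and sham 17 alone held 11932 CPM of Ttr against a sham median of 21.6.

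Camera called 11 of 41 lists at the low loading in the striatum. The 7 higher lists were astrocytes (adjusted p 2.51e-09), endothelial cells, oligodendrocytes and myelin (24 of 24 members higher; the myelin protein Mbp 0.40 ± 0.20), mural cells, oligodendrocyte precursors (11 of 11; Olig2 0.31 ± 0.17), microglia (17 of 20; the growth factor receptor Csf1r 0.45 ± 0.20) and inflammation (14 of 18; the lipopolysaccharide receptor Tlr4 0.78 ± 0.28, the interleukin receptor Il1r1 0.80 ± 0.29). Their largest adjusted p was 0.0043, and adjusted p = 0.322 to 0.695 with an estimated correlation. The 4 lower lists were the respiratory chain (4.47e-08), ependymal cells (11 of 12 lower, median -0.40), ribosomal proteins (0.00169) and choroid plexus (0.0228), with adjusted p = 0.731 to 0.797 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 9 members passed, 8 of them in the choroid plexus list. Without the libraries of animal 17 the choroid plexus list turned to the other sign (adjusted p 0.586) and the list of projection neurons was called lower (3.14e-06). The choroid plexus call was also lost without low 37, sham 48 or low 53 (0.0552 to 0.0573). The call of ependymal cells was lost without sham 17, low 37 or low 53 (0.0692, 0.0779 and 0.142). That of ribosomal proteins was lost without low 20, sham 48 or sham 49 (0.106, 0.132 and 0.864), and that of microglia without sham 17 or low 37 (0.0582 and 0.0523). Among single genes edgeR called 0 (471 at unadjusted p under 0.05, 296 higher and 175 lower, where chance gives 613), and DESeq2 and limma-voom called 0. The smallest adjusted p in edgeR was 0.685, for Rhbdf1 (303008), an inactive protease of the rhomboid family (0.58 ± 0.12). Next among the higher genes were Sh3d21 (0.83 ± 0.21), Elf2 (0.34 ± 0.10), Sspn (0.44 ± 0.13) and Parpbp (3.08 ± 0.91), and among the lower genes Slc16a8 (-2.43 ± 0.69), Slc4a5 (-3.87 ± 1.15), Kl (-3.82 ± 1.14) and Kcne2 (-2.28 ± 0.68), all with an adjusted p of 0.905. Kl turned to 0.50 with DESeq2, 0.90 with limma-voom, 0.43 without libraries standing apart and 0.46 without animal 17, and with limma-voom Slc4a5 turned to 0.36 and Ttr to 1.00. The remaining 30 lists had adjusted p from 0.0618 to 0.936.

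In the striatum at the medium loading, vascular and microglial transcripts stood above sham and transcripts of the neighbouring septum, pallidum and thalamus stood below, as did, for the most part through sham 17, those of the choroid plexus. Of 23 transcripts of projection neurons 22 were higher (median 0.39; the guanine exchange factor Rasgrp2 0.43 ± 0.38, the tachykinin precursor Tac1 0.48 ± 0.45, n = 8 and 8), with a list mean of 8.48 ± 0.17 log2 CPM against 7.84 ± 1.36 in sham, where sham 17 had 4.54. Without the libraries of animal 17 the list of projection neurons was not called (adjusted p 0.117). Of 16 transcripts of the septum, pallidum and thalamus 13 were lower (median -1.16), among them Trpc4, a cation channel (-1.34 ± 0.42), Calb2, the calcium buffer calretinin (-2.70 ± 0.91), Zic1, a transcription factor (-2.23 ± 0.79), and Slc17a6, a vesicular glutamate transporter (-4.71 ± 1.73). All 11 choroid plexus transcripts were lower (median -2.89), with Ttr at -6.72 ± 1.40, Slc4a5 (297386), a bicarbonate transporter, at -5.11 ± 1.12 and Kl (83504), the co-receptor klotho, at -5.03 ± 1.11. Without animal 17 Ttr stood at -3.34, and the difference of choroid plexus library means went from -1.15 to -0.47. Sham 48, with the next highest Ttr in sham, was kept in both. The library means of the septum, pallidum and thalamus list fell by 0.76 log2 units, from 3.34 ± 0.80 in sham, where sham 48 had 4.80, to 2.58 ± 0.12 (exact permutation over libraries, p = 0.000932; adjusted p 0.0382 over 41 lists), the only list in any comparison to pass that test. It still passed when any 1 sham library was left out (0.55 log2 units lower without sham 48, 0.63 without sham 17). It did not pass when any 1 of the 8 medium libraries was left out (adjusted p 0.268 to 0.465), although the difference stayed between -0.74 and -0.78. The spreads of the 2 groups were unequal, and the permutation p then depends on which group is larger. These passes and losses therefore do not show that the result rests on single medium libraries or is free of single sham libraries. The adjustment covered the lists of this comparison alone, not those of all comparisons, and the test was chosen after seeing the data.

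Camera called 16 of 41 lists at the medium loading in the striatum. Higher were endothelial cells (8.38e-08; 18 of 18 members; the transporter Slco1a4 0.40 ± 0.17), microglia (19 of 20; the protease Ctss 0.39 ± 0.17), projection neurons (2.05e-06), astrocytes (18 of 19), ribosomal proteins (78 of 79, median 0.19), mural cells (14 of 14), the circadian clock (15 of 16; the repressor Nr1d2 0.30 ± 0.10), dopamine signalling (13 of 16; the monoamine oxidase Maob 0.30 ± 0.14), the respiratory chain (71 of 71, median 0.12) and the interferon response (16 of 23; 0.0448). Lower were choroid plexus (3.47e-07), septum, pallidum and thalamus (0.00019), ependymal cells (11 of 12), synaptic vesicle and plasticity (15 of 22; the synapsin Syn2 -0.55 ± 0.22), cortical excitatory neurons (12 of 15; the transcription factor Neurod6 -2.12 ± 1.00) and cerebellar granule cell genes (10 of 13; 0.0263), the last of which shares Calb2, Zic1 and Cbln1 with neighbouring tissue. For these 16 lists adjusted p = 0.317 to 0.869 with an estimated correlation, and no member passed over all genes. Adjusted over the list alone 21 members passed, 11 in the choroid plexus and 5 in the septum, pallidum and thalamus list. The respiratory chain turned sign without medium 41 (adjusted p 0.356) and lost its call without any 1 of 7 libraries. Ribosomal proteins lost the call without medium 41 or 8 (0.482 and 0.145) and ependymal cells without medium 10 or 54 (0.120 and 0.0678). Granule cell genes lost it without medium 8, medium 41 or sham 48 (0.118, 0.132 and 0.0770), cortical neurons without any 1 of 5 libraries (up to 0.233) and the interferon response without any 1 of 9 (up to 0.459). Without sham 17 the difference of library means went from 0.44 to 0.14 for dopamine signalling and from 0.19 to 0.10 for the circadian clock, and without sham 18 from 0.21 to 0.13 for astrocytes, all still called. Ribosomal transcripts were highest in medium 41 (8.92) and medium 8 (8.73 log2 CPM), and without libraries standing apart the ribosomal, respiratory chain and cortical lists turned sign (the respiratory chain called lower, adjusted p 0.00013). The 2 medium libraries left out stood apart on the ribosomal list itself, so the ribosomal and respiratory chain turns follow in part from that choice. Among single genes edgeR called 0 (453 at unadjusted p under 0.05, 113 higher and 340 lower), and DESeq2 and limma-voom called 0. The smallest adjusted p was 0.276, for Ttr, Slc4a5, Kl and the chloride channel Clic6 (304081; -4.33 ± 0.95), then 0.334 for Mfrp (-5.76 ± 1.32). The higher genes with the smallest p were Stk17b (0.54 ± 0.17), Kyat3 (0.44 ± 0.14), Cebpg (0.29 ± 0.09), Tmem243 (0.42 ± 0.14) and Lactb (0.42 ± 0.13). The remaining 25 lists had adjusted p from 0.0509 to 0.971.

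In the striatum at the high loading, astrocyte, microglial and vascular transcripts stood above sham by small amounts, and, with sham 17 included, choroid plexus and ependymal transcripts stood below. All 19 astrocyte transcripts were higher (median 0.21), with Glul, glutamine synthetase, at 0.24 ± 0.13 and Gja1, a gap junction protein, at 0.26 ± 0.15 (n = 8 and 8). All 14 mural (median 0.25; Rgs5 0.39 ± 0.23) and all 18 endothelial transcripts (median 0.17; the lipid transporter Mfsd2a 0.17 ± 0.12) were higher, as were 18 of 20 microglial transcripts (the purine receptor P2ry12 0.37 ± 0.19). The difference of library means went from 0.16 to 0.09 for endothelial cells and from 0.17 to 0.09 for microglia without sham 17, from 0.21 to 0.13 for astrocytes without sham 18, and to 0.27 for endothelial cells without high 28. Ttr stood at -6.17 ± 1.37, Slc4a5 at -4.67 ± 1.08, Kl at -4.64 ± 1.07 and Clic6 at -3.78 ± 0.91, and the sham 17 library held 11932 CPM of Ttr against a sham median of 21.6. Ttr stood at -2.79 without animal 17 and turned to 0.24 with limma-voom. Projection neuron transcripts had a median of 0.00, with high 13 at 5.23 and high 44 at 7.25 log2 CPM.

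Camera called 13 of 41 lists at the high loading in the striatum. Higher were astrocytes (6.16e-08), mural cells, endothelial cells, microglia, ribosomal proteins (76 of 79, median 0.20; high 28 at 9.43 log2 CPM), granule cell precursors and cell cycle (12 of 13; the replication helicase subunit Mcm2 0.40 ± 0.18, the proliferation marker Mki67 0.63 ± 0.45) and the circadian clock (13 of 16; 0.000619; Nr1d2 0.21 ± 0.10). Lower were choroid plexus (9.81e-07; 11 of 11), ependymal cells (11 of 12; the cilia regulator Foxj1 -0.84 ± 0.48), septum, pallidum and thalamus (0.000616), cortical excitatory neurons (9 of 15; Neurod6 -1.51 ± 0.96), meningeal and perivascular fibroblasts (16 of 18; the growth factor Igf2 -1.37 ± 0.48, the sulfate transporter Slc13a4 -1.77 ± 0.53) and immediate early genes (20 of 23; 0.0157; the kinase Sik1 -0.42 ± 0.26). The septum list was called lower with a median of -0.02, a mean of 0.01 and 8 members on each side, so the mean of its fold changes and its test differed in sign, while its library means went with the test (2.95 against 3.34 log2 CPM in sham). The difference for granule cell precursors and cell cycle went from 0.26 to 0.16 without high 44. For these 13 lists adjusted p = 0.357 to 0.905 with an estimated correlation, and no member passed over all genes. Adjusted over the list alone 14 members passed, 10 in the choroid plexus and 3 in the fibroblast list. Without the libraries of animal 17 the fibroblast list turned sign (called higher, adjusted p 0.0419) and the choroid plexus call ended (adjusted p 0.762), as did those of the circadian clock (0.370), ependymal cells (0.0578), microglia (0.0514) and ribosomal proteins (0.401). Ribosomal proteins turned sign and were called lower without high 28 (adjusted p 0.00699), and were not called without high 59 (0.900), sham 32 (0.0522) or sham 34 (0.0638). Calls were also lost for fibroblasts without high 14 or 58 (0.0767 and 0.0625) and for the septum list without high 28 or sham 48 (0.0747 and 0.0644). They were lost for cortical neurons without sham 3, high 28 or sham 49 (0.0968, 0.192 and 0.0655) and immediate early genes without any 1 of 8 libraries (up to 0.426). Among single genes edgeR called 0 (141 at unadjusted p under 0.05, 64 higher and 77 lower), and DESeq2 and limma-voom called 0. The smallest adjusted p was 0.644, for Ttr, Slc4a5 and Kl, followed by Clic6 (0.843) and Tmem72 (-3.69 ± 0.91; 0.20 with limma-voom). Rhbdf1 (0.39 ± 0.11), the chemokine-like receptor Cmklr1 (0.69 ± 0.23), Actl6a (0.25 ± 0.09), Havcr2 (0.49 ± 0.18) and Nfatc4 (0.63 ± 0.23) had the smallest p among the higher genes. The remaining 28 lists had adjusted p from 0.185 to 0.989.

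Across all 4 groups of the striatum, Ttr, Slc4a5 and Kl passed the test of any exposure (edgeR, adjusted p 0.0266, 0.0471 and 0.0471). Each is a transcript of the choroid plexus epithelium. Mean Ttr was 1626 ± 4178 CPM in sham (n = 8), 36.6 ± 28.0 in low (n = 6), 15.0 ± 12.5 in medium (n = 8) and 22.3 ± 9.60 in high (n = 8), with medians of 21.6, 28.5, 12.0 and 22.9. Slc4a5 stood at 27.1 ± 69.7, 1.86, 0.773 and 1.02 CPM, with medians of 0.990, 1.26, 0.837 and 0.640. Kl stood at 30.5 ± 81.7, 2.15, 0.908 and 1.19 CPM, with medians of 0.966, 1.78, 0.864 and 1.40. Sham 17 held 11932 CPM and sham 48 held 979 CPM of Ttr. Clic6 (adjusted p 0.0757), Parpbp (0.110), Tmem72 (0.110), Mfrp (0.126), Kcne2 (0.423), Igfbp2 (0.552) and Rhbdf1 (0.552) came next, and 248 genes had an unadjusted p under 0.05.

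The calls for any exposure in the striatum were lost when single libraries were left out: 0 genes passed without sham 17 (edgeR). The log2 fold change of Ttr without that animal was -2.08 (low), -3.34 (medium) and -2.79 (high). Those fits kept sham 48, which had the next highest Ttr in sham, so the remaining difference was not separated from that library. Median Ttr over all libraries was 21.6 CPM in sham, 28.5 in low, 12.0 in medium and 22.9 in high. The count of genes passing was also 0 without low 7, 20, 22 or 53, without medium 10, 24, 26, 40, 54 or 57, and without high 13, 14, 27, 28, 43, 44, 58 or 59. It was 1 (Ttr) without medium 8, medium 41, sham 48 or low 51, 4 (with Clic6) without sham 1, 18, 32 or 49, and 6 without sham 3 or low 37. DESeq2 and limma-voom called 0 genes for any exposure, with p of 0.000386 and 0.133 for Ttr over all 30 libraries. For the linear trend with percent loading edgeR, DESeq2 and limma-voom called 0 genes in the striatum (edgeR, 119 at unadjusted p under 0.05, 30 higher and 89 lower; smallest adjusted p 0.694). Ttr stood at -0.58 ± 0.13, Slc4a5 at -0.47 ± 0.11, Kl at -0.46 ± 0.11, Clic6 at -0.36 ± 0.09 and Tmem72 at -0.36 ± 0.09 log2 units per percent. Among the genes with a positive slope, Trmo (0.05 ± 0.02), Usp12 (0.02 ± 0.01), 2810025M15Rikl (0.04 ± 0.02), Fam163a (0.05 ± 0.02) and Utp23 (0.03 ± 0.01) had the smallest p.

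**Figure D2:**
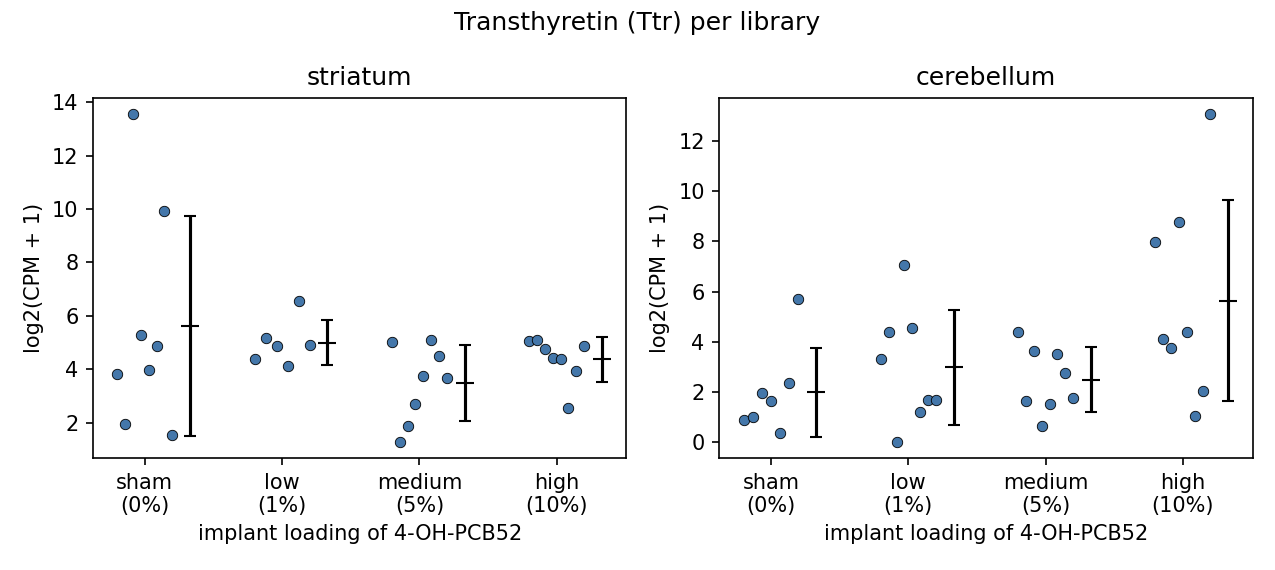
Ttr in each library, as log2(CPM + 1), by exposure group in the striatum and the cerebellum. Each point is a library and bars are mean ± SD.

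In the cerebellum at the low loading, transcripts of myelin, cholesterol synthesis and the brainstem or deep cerebellar nuclei stood above sham and transcripts of Purkinje cells stood below, for the most part through 1 library, low 22. All 24 myelin transcripts were higher (median 0.83), among them Mal, a myelin membrane protein (1.01 ± 0.42), Enpp6, a choline phosphodiesterase of new oligodendrocytes (1.17 ± 0.49), and Opalin (0.82 ± 0.37, n = 8 low and 7 sham). Of 25 cholesterol synthesis transcripts 23 were higher (median 0.31; Idi1 0.37 ± 0.18, Hmgcs1 0.61 ± 0.31, Sqle 0.40 ± 0.21, enzymes of the sterol pathway). Of 21 Purkinje cell transcripts 18 were lower (median -0.22; the glutamate transporter Slc1a6 -0.51 ± 0.37, Pcp2 -0.65 ± 0.66). Without low 22 the difference of library means went from 0.50 to 0.18 for myelin, from 0.22 to 0.06 for cholesterol synthesis, from 0.71 to 0.34 for the brainstem list and from -0.48 to -0.06 for Purkinje cells. Of these lists myelin alone was then called (adjusted p 0.435 for Purkinje cells, 0.173 for cholesterol synthesis and 0.171 for brainstem). Tac1 (24806) stood at 4.82 ± 1.35 (-0.15 with limma-voom), Slc17a6 (84487) at 4.45 ± 1.32 and the bone matrix protein Spp1 at 3.87 ± 1.40, genes of the brainstem list, in a group where low 22 had a granule cell mean of 4.30 log2 CPM and 1.71 CPM of Gabra6.

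Camera called 16 of 42 lists at the low loading in the cerebellum. Higher were myelin (2.85e-16), cholesterol synthesis (2.37e-07), astrocytes (17 of 19; Fgfr3 0.59 ± 0.24), brainstem and deep cerebellar nuclei (6 of 8; the neurofilament Nefm 0.91 ± 0.37), ependymal cells (5 of 6), GABA and glycine signalling (17 of 24; the GABA transporter Slc6a11 2.03 ± 0.70, the receptor subunit Gabra5 3.23 ± 1.33), oligodendrocyte precursors (10 of 11; Olig2 0.82 ± 0.36), heat shock (12 of 13; the chaperone Hsph1 0.29 ± 0.20), microglia (13 of 20; Tmem119 0.63 ± 0.37), striatal projection neuron genes (11 of 17, led by Tac1) and synaptic vesicle and plasticity (17 of 22; 0.0366; the neuropeptide precursor Vgf 1.08 ± 0.54). Lower were Purkinje cells (1.53e-08), cerebellar granule cells (15 of 19, median -0.08), meningeal and perivascular fibroblasts (20 of 20, median -1.05; Serpinf1 -1.55 ± 0.71), ribosomal proteins (77 of 78, median -0.44) and the interferon response (17 of 23; 0.0401; Irf9 -0.23 ± 0.13). For these 16 lists adjusted p = 0.180 to 0.960 with an estimated correlation, and no member passed over all genes. Adjusted over the list alone 7 members passed, 5 of them in the brainstem list. Granule cells turned sign without low 22 (adjusted p 0.431), and the difference of astrocyte library means went from 0.26 to 0.17. Without sham 48 sign was turned by fibroblasts (0.351), the interferon response (0.502) and ribosomal proteins, which were then called higher (0.00521). Sham 48 had a fibroblast mean of 7.77 log2 CPM against a sham mean of 4.66, and the fibroblast call was lost without low 37 too (0.271). Calls were lost without low 22 for microglia (0.918), oligodendrocyte precursors (0.431), heat shock (0.328), striatal projection neuron genes (0.275) and ependymal cells (0.173). They were lost without sham 48 for GABA and glycine signalling (0.901), synaptic vesicle and plasticity (0.915) and precursors (0.131). Apart from precursors (lost without low 7 too, 0.0552), each of these lists, ribosomal proteins and the interferon response lost its call without any 1 of 4 to 12 libraries. Without libraries standing apart, low 22 and sham 48 among them, 5 lists were called, and the granule cell, fibroblast and myelin lists turned sign. Among single genes edgeR called 0 (182 at unadjusted p under 0.05, 120 higher and 62 lower, where chance gives 597), and DESeq2 and limma-voom called 0. The peptidase gene Ecel1, 6330403K07Rikl (4.29 ± 1.23) and Baiap3 (2.29 ± 0.68) followed Tac1 among the higher genes. With limma-voom Ecel1 turned to -0.45 and 6330403K07Rikl to -0.03, the latter also without libraries standing apart (-0.08). Csad (-0.61 ± 0.20), the platelet chemokine Pf4 (-2.40 ± 0.86), Tekt5 (-0.84 ± 0.32), the kinase Pim1 (-0.54 ± 0.20) and Tmem198b (-0.35 ± 0.13) had the smallest p among the lower genes, and the smallest adjusted p was 1.00. The remaining 26 lists had adjusted p from 0.0682 to 0.995.

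In the cerebellum at the medium loading, microglial transcripts stood above sham, as did those of myelin and sterol synthesis with medium 8 included. Transcripts of vessels stood below, as did those of granule cells with medium 40 included. The difference of granule cell library means went from -0.27 to -0.05 without medium 40, and to -0.42 without sham 48. Of 20 microglial transcripts 15 were higher (median 0.25), among them Tmem119, a surface protein of resident microglia (0.86 ± 0.37), Cx3cr1, the fractalkine receptor (0.72 ± 0.35), and P2ry12 (0.58 ± 0.32, n = 8 medium and 7 sham). Without sham 48 the difference of microglial library means went from 0.32 to 0.56. All 20 fibroblast transcripts were lower (median -0.95; the collagen Col1a1 -1.05 ± 0.50), as were 14 of 18 endothelial transcripts (the adhesion protein Pecam1 -0.39 ± 0.23). Sham 48 had a fibroblast mean of 7.77 log2 CPM. Without it the difference of fibroblast library means turned from -0.36 to 0.15 (list not called, adjusted p 0.348). Slc17a6 stood at 3.19 ± 1.27, Spp1 at 3.27 ± 1.36 and Tac1 at 2.73 ± 1.32 in the brainstem list, and medium 40 had a granule cell mean of 6.68 log2 CPM and 195 CPM of Gabra6.

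Camera called 14 of 42 lists at the medium loading in the cerebellum. Higher were microglia (0.000104), the respiratory chain (71 of 71, median 0.20; Sdha 0.21 ± 0.15), myelin (23 of 24, median 0.41), cholesterol synthesis (21 of 25, median 0.19), astrocytes (13 of 19; Gfap 0.46 ± 0.29), ependymal cells (4 of 6; Foxj1 0.87 ± 0.40), heat shock (11 of 13), the unfolded protein response (15 of 17; the chaperone Dnajb9 0.23 ± 0.11), ribosomal proteins (73 of 78, median 0.09), NRF2 and antioxidant genes (19 of 25, median 0.08) and brainstem and deep cerebellar nuclei (8 of 8; 0.0406). Lower were fibroblasts (0.00286), endothelial cells (0.0124) and cerebellar granule cells (16 of 19; 0.0205, median -0.19). For these 14 lists adjusted p = 0.582 to 0.820 with an estimated correlation, and no member passed over all genes. Adjusted over the list alone 5 members passed, 4 of them in the list of blood, which was not called (adjusted p 0.555, median -3.08; library means 1.27 ± 1.06 against 1.64 ± 2.96 log2 CPM in sham, with 7.51 in sham 48). Ribosomal transcripts were highest in medium 24 (9.74 log2 CPM). Without it ribosomal proteins turned sign (adjusted p 0.260) and the respiratory chain was not called (0.834). Without medium 8 myelin (0.991), cholesterol synthesis (0.176) and astrocytes (0.114) were not called. Without sham 48 these were not called either (0.189, 0.132 and 0.132), nor were endothelial cells (0.477) and heat shock (0.132). Without medium 40 granule cells (0.890) and astrocytes (0.0693) were not called. Fibroblasts lost the call without medium 8, 10 or 54 too (0.176, 0.150 and 0.271), and granule cells without sham 1 or medium 8 (0.121 and 0.0528). Heat shock lost it without medium 57 (0.0516) and endothelial cells without medium 10, 54 or 57 (0.0513 to 0.0615). The brainstem, NRF2, ribosomal and unfolded protein lists lost it without any 1 of 11, 9, 9 and 5 libraries. Without libraries standing apart 4 lists were called, none with the direction it had among the 14. Ribosomal proteins (adjusted p 2.67e-22) and the respiratory chain (1.89e-13) were then called lower, and the myelin, brainstem, ependymal, heat shock, NRF2 and unfolded protein lists turned sign too. All 4 medium libraries and the 1 sham library left out stood apart on the ribosomal list itself. The lower ribosomal and respiratory chain calls thus follow in part from that choice. Among single genes edgeR called 0 (170 at unadjusted p under 0.05, 122 higher and 48 lower; smallest adjusted p 0.999), and DESeq2 and limma-voom called 0. The smallest p belonged to Rtn4rl2 (2.89 ± 0.84), Enc1 (2.65 ± 0.84), C1ql3 (2.61 ± 0.84), C9h2orf69 (0.33 ± 0.11) and Icam5 (3.67 ± 1.21), higher, and Clic3 (-0.91 ± 0.24), the haemoglobin gene Hba-a3 (-2.86 ± 0.93), Lmf2 (-0.27 ± 0.09), Lrwd1 (-0.36 ± 0.12) and Casq1 (-0.85 ± 0.30), lower. Enc1 turned to -0.24 with DESeq2, -0.04 with limma-voom and -0.02 without libraries standing apart. The remaining 28 lists had adjusted p from 0.120 to 0.990.

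In the cerebellum at the high loading, transcripts of ribosomal proteins and of the respiratory chain stood far above the sham mean in 3 of the 8 libraries, high 43, 28 and 59, as they did in sham 48. Transcripts of vessels and synapses stood below sham, in large part through high 43. Without it the difference of library means went from -0.32 to -0.13 for GABA and glycine signalling and from -0.31 to -0.10 for glutamate signalling. For synaptic vesicle and plasticity it went from -0.32 to -0.18. Without sham 48 these 3 differences were larger (-0.50, -0.56 and -0.48). Of 78 ribosomal protein transcripts 77 were higher (median 1.78; Rpl37l1 2.21 ± 0.77, Rpl35a 2.07 ± 0.75, n = 8 high and 7 sham), as were 70 of 71 respiratory chain transcripts (median 1.49; the complex III subunit Uqcr10 2.63 ± 0.85, the complex I subunit Ndufa5 1.44 ± 0.53). Ttr stood at 7.07 ± 1.86, with 8607 CPM in high 59, 439 in high 28 and 249 in high 13 against a sham mean of 8.82 ± 18.5. Pcp2 had a median of 318 CPM in high and 397 CPM in sham, with 6779 CPM in high 43. Plppr1 (298062), a phospholipid phosphatase-related membrane protein, stood at -0.74 ± 0.16, the smallest p of the comparison.

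Camera called 10 of 42 lists at the high loading in the cerebellum. Higher were ribosomal proteins (1.27e-17), the respiratory chain (7.82e-14), myelin (21 of 24; 0.00247; the chaperone Cryab 1.59 ± 0.69), NRF2 and antioxidant genes (19 of 25; 0.0354; the sulfiredoxin Srxn1 0.54 ± 0.21, the peroxidase Gpx4 1.48 ± 0.62, the ferritin Fth1 1.61 ± 0.70) and choroid plexus (8 of 12; 0.0458; the folate receptor Folr1 3.63 ± 1.29). Lower were endothelial cells (14 of 18; 5.60e-05; the tight junction protein Ocln -0.38 ± 0.16), GABA and glycine signalling (19 of 24; 0.0123; the vesicular transporter Slc32a1 -0.33 ± 0.15), glutamate signalling (25 of 34), synaptic vesicle and plasticity (18 of 22; the complexin Cplx1 -0.36 ± 0.16) and fibroblasts (19 of 20; 0.0329, median -1.21). For all 10 lists adjusted p = 0.882 with an estimated correlation, and no member passed over all genes. Adjusted over the list alone 129 members passed, 75 ribosomal and 48 of the respiratory chain. Without sham 48 the difference of fibroblast library means turned from -0.44 to 0.08 (list not called, adjusted p 0.843), and myelin (0.113) and endothelial cells (0.0630) were not called. Without high 43 the difference went from 0.84 to 0.38 for ribosomal proteins and from 0.63 to 0.26 for the respiratory chain, and without high 28 to 0.52 and 0.39, both still called. It went from -0.42 to -0.26 for endothelial cells without high 43 and from 0.36 to 0.23 for myelin without high 28, also still called. Fibroblasts lost the call without high 13, 14, 27 or 44 too (up to 0.559). GABA and glycine signalling lost it without sham 1, high 43 or high 59 (0.0615, 0.0952 and 0.0766) and synaptic vesicle and plasticity without the same 3 (0.0615, 0.0859 and 0.0612). Choroid plexus, glutamate signalling and NRF2 lost it without any 1 of 9, 7 and 7 libraries. Without libraries standing apart, which left 5 high and 6 sham libraries, ribosomal proteins and the respiratory chain turned sign and were called lower (adjusted p 1.34e-18 for each), and the endothelial, GABA, glutamate, synaptic and NRF2 lists turned sign too. All 3 high libraries and the 1 sham library left out stood apart on the ribosomal list itself. The lower ribosomal and respiratory chain calls thus follow in part from that choice and are no independent test. The ribosomal library means differed by 0.84 log2 units between high and sham (exact permutation p = 0.385), with medians of 7.22 in high and 7.45 in sham. Among single genes edgeR called 0 (1394 at unadjusted p under 0.05, 1256 higher and 138 lower), limma-voom called 0 and DESeq2 called 1, Ttr, and 0 without libraries standing apart. The smallest adjusted p in edgeR was 0.417, shared by all the genes named next. Ccdc167 (1.01 ± 0.28), the neuropeptide galanin gene Gal (2.78 ± 0.78), Mfrp (3.08 ± 0.87) and Cdo1 (1.21 ± 0.34) followed Ttr among the higher genes, and Tp53i11 (-0.85 ± 0.26), the metalloprotease Mmp14 (-0.99 ± 0.32), St6galnac2 (-1.02 ± 0.34) and Zyx (-0.43 ± 0.15) followed Plppr1 among the lower. The remaining 32 lists had adjusted p from 0.0709 to 0.885.

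Ribosomal protein transcripts of a rat's striatum followed those of its cerebellum. Over 29 rats with both regions, library means taken within exposure groups had a Spearman rho of 0.733 (permutation p = 3e-05, adjusted 9e-05 over 3 relations) and a Pearson r of 0.674 (permutation p = 0.00019, adjusted 0.000285). Without the 2 rats farthest from the median r was 0.645 and rho 0.693 (n = 27). Without removing group means r was 0.672 (permutation p = 0.0005, adjusted 0.0005) and rho 0.675 (p = 0.0001, adjusted 0.00015).

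**Figure D3:**
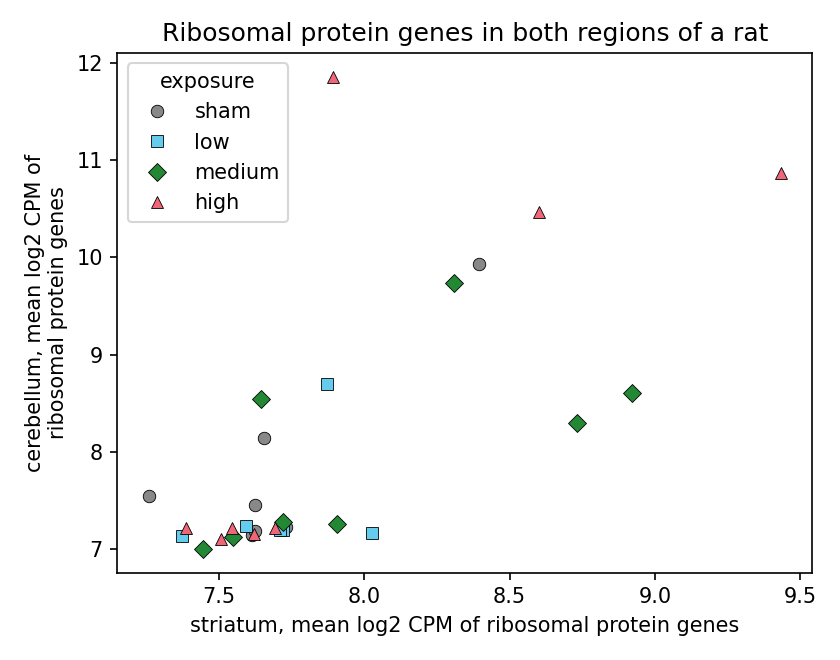
Mean log2 CPM over ribosomal protein genes in the striatum and the cerebellum of the same rat, for the 29 rats with both regions, coloured by exposure group. Each point is a rat.

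Across all 4 groups of the cerebellum no gene passed in edgeR, where Wfdc10a (685216), a protease inhibitor family member, Ttr and the T cell co-receptor Cd8a (24930) shared the smallest adjusted p of 0.0733. Plppr1 (0.0858), Rtn4rl2, Chtf18, Icam5, Gng13, Ddn (0.161 each) and Spag5 (0.197) came next, and 1236 genes had an unadjusted p under 0.05. Limma-voom called 1 gene, Plppr1, and DESeq2 called 153, and 0 without libraries standing apart. With high 13 or high 58 left out edgeR called 1 gene (Wfdc10a), with high 14 or high 44 left out 3 (Cd8a, Ttr and Wfdc10a), and with sham 48 left out 3 (Ddn, Ttr and Wfdc10a).

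For the linear trend in the cerebellum 2464 genes had an unadjusted p under 0.05, 2249 with a positive and 215 with a negative slope, and edgeR called 0 at a smallest adjusted p of 0.0755. Ttr stood at 0.65 ± 0.13, Wfdc10a at 0.25 ± 0.05, Gng13, a G protein subunit, at 0.25 ± 0.05, Chtf18, a clamp loader of replication, at 0.22 ± 0.04 and Cdo1, cysteine dioxygenase, at 0.13 ± 0.03 log2 units per percent loading. Gng13 turned to -0.02 and Chtf18 to -0.01 without libraries standing apart, and Gng13 turned sign with limma-voom too. Plppr1 (-0.07 ± 0.02), Zyx (-0.05 ± 0.01), Mmp14 (-0.09 ± 0.03), Ext2 (-0.03 ± 0.01) and Tapbp (-0.04 ± 0.01) led the negative slopes, all with the same adjusted p of 0.0755. DESeq2 called 901 genes, and 0 without libraries standing apart, and limma-voom called 0. The edgeR count depended on single libraries: it was 1635 without sham 48, 1062 without high 13, 966 without high 14, 887 without high 27, 992 without high 44 and 997 without high 58, and 0 without any other library. Sham 48 had a raised ribosomal mean (9.93 log2 CPM), and those 5 high libraries had none above 7.22.

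In the fit that took all 61 libraries as independent, the high versus sham change of Ttr differed between the regions. That call was lost once the 2 regions of a rat were paired. The difference, striatum minus cerebellum, was -13.25 ± 2.35 log2 units (edgeR interaction, adjusted p 0.00744), the single gene past the threshold of 12616, while 1015 genes had an unadjusted p under 0.05, 92 positive and 923 negative. It combined the Ttr of sham 17 in the striatum with that of the high group in the cerebellum, where high 59 held the most. Further choroid plexus genes came next, Cldn2, a claudin (-7.75 ± 1.61, adjusted p 0.0678), Slc4a5 (-5.71 ± 1.21, 0.0678), Mfrp (-7.07 ± 1.53, 0.0688) and the secretoglobin Scgb1c1 (adjusted p 0.0988). With a block for the animal, which pairs the regions of 29 rats, Ttr stood at -5.06 with an adjusted p of 0.869, and 0 genes passed. Without the libraries of animal 17 it stood at -9.71 (adjusted p 0.284), and 0 genes passed. DESeq2 called 4 genes, among them Ttr, Folr1 and Scgb1c1. Positive differences were led by Rhbdf1 (0.53 ± 0.16), Pawr (1.25 ± 0.40), Slc52a3 (0.93 ± 0.31), Smarcal1 (0.51 ± 0.17) and Nfatc4 (1.66 ± 0.56), each with an adjusted p of 0.591.

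Apart from Ttr, the named genes of pathways known as targets of polychlorinated biphenyls and their metabolites did not pass in any comparison. The striatal call of Ttr was lost without sham 17, which held 11932 CPM. In the cerebellum high 59 held 8607 CPM, but neither DESeq2, which called Ttr there, nor the interaction was run without that library alone. Median Ttr was 21.6, 28.5, 12.0 and 22.9 CPM in the striatum (sham, low, medium, high) and 2.14, 5.53, 4.02 and 18.1 CPM in the cerebellum. Without the libraries of animal 17 edgeR called no gene in the striatum or in the interaction. In the cerebellum edgeR called none with all libraries either, so leaving out that animal could not lower the count there. Nqo1, a quinone reductase under the antioxidant regulator NRF2, stood at 16.5, 14.2, 14.8 and 15.3 CPM in the striatum (sham, low, medium, high) and at 18.9, 16.3, 19.5 and 22.7 in the cerebellum. Hmox1, haem oxygenase, stood at 7.24, 8.14, 7.92 and 8.22 CPM and at 7.71, 7.57, 8.07 and 9.43. The thyroid hormone-responsive genes Klf9 (133, 149, 159 and 141 CPM; cerebellum 126, 140, 126 and 111) and Hr (54.1, 69.1, 47.4 and 54.6 CPM; cerebellum 194, 168, 145 and 157) had log2 fold changes between -0.42 ± 0.38 (Hr, cerebellum medium) and 0.35 ± 0.24 (Hr, striatum low). Cyp1b1, a cytochrome P450 under the aryl hydrocarbon receptor, stood at 2.51, 1.76, 1.51 and 1.15 CPM in the cerebellum (high versus sham -1.11 ± 0.71, adjusted p 0.550). The cerebellar log2 fold change of Cyp1b1 turned to 0.72, 0.31 and 0.23 (low, medium, high) without libraries standing apart. Those of Nqo1 turned to -0.21 (medium) and -0.12 (high), of Hmox1 to 0.09, -0.13 and -0.05, and of Klf9 and Hr at the high loading to 0.19 and 0.01. The transcript of tyrosine hydroxylase, Th, was near the floor, at 1.21, 1.21, 0.611 and 0.954 CPM in the striatum. Cyp2b1 and Ryr1, and Cyp1a1 in the striatum, are not analysed here. The 95% interval lay within 2-fold of no change for 85.1, 88.1 and 90.4% of genes in the striatum (low, medium, high), and for 65.9, 63.7 and 54.8% in the cerebellum.

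**Figure D4:**
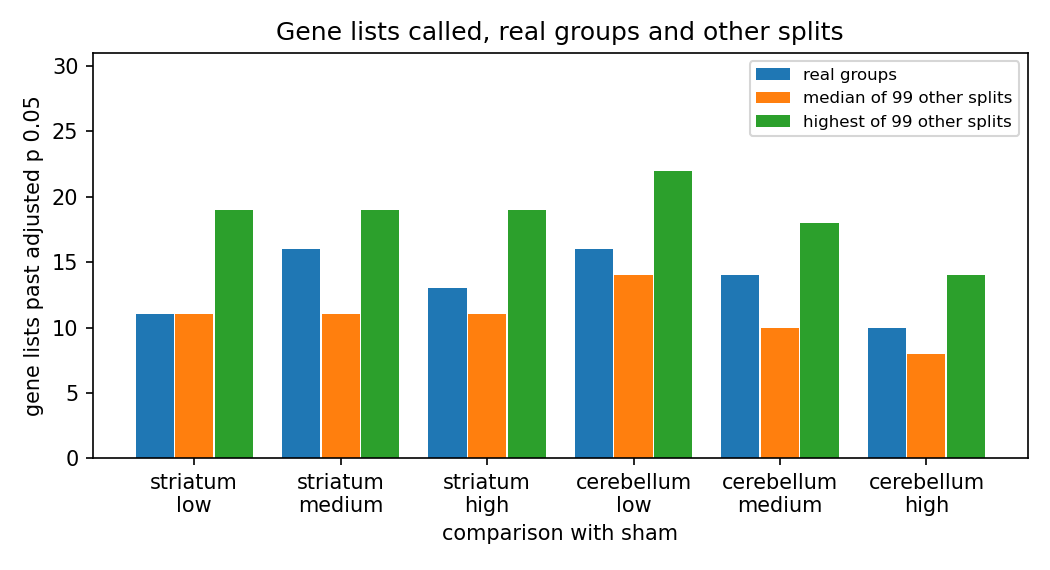
Number of gene lists called by camera in each loading versus sham comparison, beside the median and the highest number over other random splits of the same libraries into groups of the same sizes.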

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

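The tests of explanations below were chosen after the values they concern had been seen, whereas the interaction test was fixed in advance. Of 76 groups of values examined, 34 had a library far from all the others of its group, where chance gives about 1 in 20 groups, or 3.8. These groups are not independent: each library was examined on several related markers, so the same library recurs. The rate of 1 in 20 holds for normally distributed values, and CPM are skewed, so it is a rough guide only.

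In the striatum, sham 17 lay far from the other sham libraries with the lowest projection neuron mean (4.54 log2 CPM), Ppp1r1b (197 CPM), Drd1 (8.36 CPM), Drd2 (8.56 CPM), Adora2a (7.97 CPM) and Penk (67.0 CPM), and the highest Ttr (11932 CPM). Low 20 had the lowest projection neuron mean of its group (5.04), Ppp1r1b (213 CPM), Drd2 (13.3 CPM), Adora2a (37.8 CPM) and Penk (82.5 CPM). Low 51 had the highest Ttr of that group (92.1 CPM), medium 41 the highest Penk (3531 CPM) and high 13 the lowest projection neuron mean (5.23).

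In the cerebellum, sham 48 lay far from the other sham libraries with the highest ribosomal mean (9.93 log2 CPM), Ttr (50.6 CPM), Pcp2 (1523 CPM) and Car8 (2284 CPM), and the lowest granule cell mean (7.49), Gabra6 (509 CPM), Cbln3 (86.3 CPM) and Zic1 (214 CPM). Low 22 had the lowest granule cell mean (4.30), Gabra6 (1.71 CPM), Cbln1 (67.2 CPM) and Car8 (15.1 CPM), and the highest Ttr (132 CPM). Medium 40 had the lowest granule cell mean (6.68) and Gabra6 (195 CPM), and medium 24 the highest Pcp2 (1735 CPM). High 59 had the highest Ttr (8607 CPM), and high 43 the highest Pcp2 (6779 CPM) and Car8 (6913 CPM). The high versus sham change of Ttr differed between striatum and cerebellum by -13.25 log2 units in the interaction test, and by -5.06 (adjusted p 0.869) with the animal as a block.

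With sham 17 included, choroid plexus transcripts stood lower in the striatum of exposed rats than in sham. Choroid plexus tissue in the punch of sham 17 may account for this: the 8 members of that list that were not called for any exposure had a median of 6.72 log2(CPM + 1) in that library, above the 3.78 of the next library. An effect of the exposure itself stays open and cannot be told apart from none. Without animal 17 the mean log2 Ttr of high minus sham was -0.11 (exact permutation p = 0.944), against -1.24 (p = 0.462, exact permutation) with all libraries, and neither shows that the groups did not differ.

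Ribosomal protein and respiratory chain transcripts stood higher in a part of the cerebellar libraries, 3 of them in the high group. A lower total of reads in the raised libraries is argued against, since the ribosomal mean rose with the total (Spearman rho 0.588 over 31 libraries, permutation p = 0.00071, adjusted 0.00071 over 3 relations; Pearson r 0.777, p = 1e-05, adjusted 3e-05, and 0.672 without 2 libraries). A difference of RNA or tissue that the whole rat or brain carried, whether from handling or from the animal, may be a part of it, as the ribosomal means of both regions went together within exposure groups (rho 0.733 over 29 rats). The exposure stays open and cannot be told apart from none, at an exact permutation p of 0.385 for high versus sham. The labels give no preparation batch per library, so batch was not tested.

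Striatal sham 17, low 20 and high 13 held few projection neuron transcripts. A swap with a cerebellar library is argued against, as the highest Gabra6 of the 3 was 2.92 CPM, against at least 195 CPM in cerebellar libraries other than low 22. Tissue of the septum, pallidum or thalamus in these punches may be the source and stays open. The list of that tissue was at least 4.23 log2 CPM in each of the 3, against a median of 2.73 over striatal libraries, but sham 48, with its projection neurons in place, reached 4.80, so the source cannot be told apart. No biological explanation was tested, since the design names none for these animals.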

How the results depend on the processing

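For the named genes and marker levels there were 1624 values of 199 results under the alternatives. Of these, 1516 kept direction and side of the threshold, 20 newly passed, 22 no longer passed, 2 moved by more than the spread between libraries and 64 turned sign. Members named under a list were covered only where they were also named as single genes or region markers. The alternatives without libraries standing apart, with covariates, with surrogate variables, without animal 17, with each library left out in turn for the lists and with exact permutation of list means were chosen after seeing the data. DESeq2 gave no p for Parpbp in the striatum, where it found an outlying count. Where no cause follows from the construction of an alternative, the cause was not tested. Changes of up to 2-fold were often beyond reach in the cerebellum. For each loading versus sham, edgeR recovered 29.9 to 32.8% of simulated 2-fold changes there, against 68.7 to 82.1% in the striatum. Depth was similar, at 5420458 to 10994625 reads per library in the cerebellum and 5850199 to 10944066 in the striatum. The median standard error of these log2 fold changes was 0.317 to 0.318 in the cerebellum and 0.184 to 0.198 in the striatum.

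The 3 genes called for any exposure in the striatum (248 at unadjusted p under 0.05) became 0 with DESeq2, limma-voom, the run block, without libraries standing apart, with covariates, with surrogate variables and without animal 17 (edgeR where no other tool is named), 11 with no filter, 10 with the filter at a mean CPM of 1, and 1 (Ntng1) with DESeq2 without libraries standing apart. DESeq2 gave 1 gene for cerebellum high (Ttr), 153 for any exposure and 901 for the trend in the cerebellum, and 4 for the interaction. Limma-voom gave 1 for any exposure in the cerebellum (Plppr1). DESeq2 without libraries standing apart gave 2 for striatum medium (Dlk1 and Ntng1) and 0 for cerebellum high, any exposure and the trend in the cerebellum. The interaction count of 1 (edgeR, 1015 at unadjusted p under 0.05) became 5 with the filter at a mean CPM of 1, and 0 with the animal as a block (29 rats), without libraries standing apart and without animal 17. The adjusted p of Ttr in the interaction ran from 8.6e-05 (DESeq2) to 0.869 (block).

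Lists called by camera numbered 17 in striatum low and 5, 4 and 3 in cerebellum low, medium and high without libraries standing apart, and 8 in striatum medium with covariates. With covariates ribosomal proteins turned sign in striatum medium and high and cerebellum low, and the respiratory chain in striatum medium and cerebellum high. Granule cells and microglia turned in cerebellum low, and glutamate signalling and NRF2 in cerebellum high. With an estimated correlation, and with fry, 0 lists were called in each of the 6 comparisons, and with exact permutation of list means 0, 1 and 0 in the striatum and 0, 0 and 0 in the cerebellum.

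Leaving out each library in turn, counts ran from 0 to 0 in all 6 loading versus sham comparisons and in the striatal trend (edgeR), from 0 to 6 for any exposure in the striatum (0 without sham 17, 6 without sham 3 or low 37), from 0 to 3 for any exposure in the cerebellum (3 without high 14, high 44 or sham 48) and from 0 to 1635 for the cerebellar trend (1635 without sham 48, and 887 to 1062 without high 13, 14, 27, 44 or 58). The lists called ran from 11 to 19 (19 without low 20), 11 to 18 and 11 to 18 in striatum low, medium and high, and from 10 to 16 (10 without low 37), 9 to 15 (9 without medium 8 or 40) and 6 to 13 (6 without sham 48) in cerebellum low, medium and high.

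The values that turned sign, none of them past the threshold in the reported fit, were these log2 fold changes against sham. DESeq2: Kl 0.496 (striatum low), Enc1 -0.244 and Ttr 1.32 (cerebellum medium). Limma-voom: Ttr 0.996, Slc4a5 0.356 and Kl 0.895 (striatum low), Hr 0.00817 (striatum medium), Ttr 0.236, Tmem72 0.196 and Drd2 -0.0552 (striatum high), in cerebellum low 6330403K07Rikl -0.0287, Tac1 -0.145, Ecel1 -0.452, Nqo1 0.0252 and Hmox1 0.0997, Enc1 -0.0402, Hmox1 -0.00487 and Ttr 0.510 (cerebellum medium), Klf9 0.123 (cerebellum high) and Gng13 -0.00196 per percent (cerebellar trend). Run block: Drd1 0.00434 (striatum high), Hmox1 0.00198 (cerebellum low) and Ttr 1.38 (cerebellum medium). Without libraries standing apart: Kl 0.429 (striatum low), Hr -0.0837 (striatum high), in cerebellum low 6330403K07Rikl -0.0802, Cyp1b1 0.719 and Hmox1 0.0857, Enc1 -0.0199, Cyp1b1 0.311, Nqo1 -0.207, Hmox1 -0.129 and Ttr 0.572 (cerebellum medium), Cyp1b1 0.229, Nqo1 -0.116, Hmox1 -0.0506, Klf9 0.186 and Hr 0.00645 (cerebellum high), and Gng13 -0.0155 and Chtf18 -0.00948 per percent (cerebellar trend). Covariates: Drd2 0.0946 (striatum low), Drd2 -0.0596 (striatum medium), Drd1 0.0767 (striatum high), Hmox1 0.0165 (cerebellum low), Hmox1 -0.00109 and Ttr 0.323 (cerebellum medium), Nqo1 -0.246, Hmox1 -0.0459, Klf9 0.0458 and Hr 0.0170 (cerebellum high). Surrogate variables: Drd1 -0.189 and Drd2 -0.295 (striatum medium), Drd2 -0.186 and Hr -0.0300 (striatum high), Hmox1 0.0194 (cerebellum low), Nqo1 -0.0388, Hmox1 -0.0495 and Ttr 0.166 (cerebellum medium) and Nqo1 -0.127 (cerebellum high). Without animal 17: Kl 0.455 (striatum low), Drd2 -0.0740 and Klf9 -0.00113 (striatum high), Nqo1 -0.0610 and Klf9 -0.0255 (cerebellum medium). Without libraries standing apart, mean Cbln3 moved to 579 CPM and Zic1 to 685 CPM in cerebellum medium.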

Other observations

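Of the lists of routes by which polychlorinated biphenyls are known to act, those for NRF2 and antioxidant genes (cerebellum medium and high) and dopamine signalling (striatum medium) were called and the following were not. None of the 3 calls held, with adjusted p = 0.811, 0.882 and 0.396 with an estimated correlation, and both NRF2 calls turned sign without libraries standing apart. The thyroid hormone list had adjusted p from 0.143 to 0.974 over the 6 comparisons, ryanodine receptor and calcium handling from 0.147 to 0.989, targets of the xenobiotic receptors CAR and PXR from 0.205 to 0.751, conjugation of phenols from 0.281 to 0.971 and steroid hormone genes from 0.304 to 0.886. Targets of the aryl hydrocarbon receptor, tested in the cerebellum alone, had adjusted p of 0.175, 0.693 and 0.873.

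The splits of libraries were fixed before the results were seen. Each count was set against 100 splits of the same libraries into groups of the same sizes, the real one included. For the lists, chance could not be excluded in any comparison: in the striatum 57 splits gave as many as the real 11 at the low loading (highest other 19), 15 gave as many as the 16 at the medium loading (19) and 33 as many as the 13 at the high loading (19). In the cerebellum 34 splits gave as many as the 16 lists at the low loading (highest other 22), 18 as many as the 14 at the medium loading (18) and 29 as many as the 10 at the high loading (14).

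For the genes, chance could not be excluded for the count of any exposure in the striatum. There 25 of 100 splits gave as many as the 3 genes (highest other 26). For the interaction 25 of 100 gave as many as 1 gene (highest other 4242). Those splits drew groups within each region, so the striatum and cerebellum of a rat could fall in different groups. In the real design the regions of a rat share its exposure. The splits therefore cannot decide how often chance gives the interaction count. For the counts of 0 genes with edgeR the splits tell nothing, since all 100 give at least 0. The highest others for the low, medium and high loadings were 11, 0 and 38 genes in the striatum and 0, 0 and 6148 in the cerebellum. They were 3194 for any exposure in the cerebellum, and 2999 (striatum) and 2947 (cerebellum) for the trend. The median of the other splits was 0 in all of these, and for the high loading in the cerebellum 7 of the others called any gene. The splits that called many more genes than the real groups may reflect a structure of the samples other than the exposure, which was not tested. The 2464 genes with an unadjusted p under 0.05 for the cerebellar trend were reached by 9 of 100 splits (highest other 5391).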
